A study of Drosophila melanogaster with 2 samples.

How the data were processed

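Jra bound to chromatin was measured by ChIP-seq with an anti-GFP antibody in whole wandering larvae of the third instar, males and females pooled, that carried a Jra transgene with a C-terminal GFP tag. Chromatin was fragmented by sonication, per the labels. The labels name 2 biological replicates, numbered 3 and 1, which form a single group. There was no replicate 2 among the samples used here.

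The authors deposited 4 peak lists for each of 2 genome builds, dm6 and dm3. Per the text files deposited with the lists, the list of each replicate was derived from its alignments and 1 further file, and the pooled list from the alignments of both replicates and that file. The further file is taken here to be the control, because the labels name a control experiment. The IDR list was derived from these 3 lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each region carries a signal value that the authors' peak caller gave it, as deposited, on a scale of its own in each list. Signals were used to rank and describe regions, and a signal in 1 replicate is not a measured multiple of that in the other. The −log10 q-values that the authors deposited reached a ceiling shared by 2367 IDR peaks, so they were not used for ranking. Summit positions were taken as the authors deposited them. They lie in the middle of most regions, of median width 440 bp in the IDR list, which limits how finely a site can be placed. The control libraries were not analysed here.

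The dm6 lists were used for the main results. No region of these lists ended beyond its chromosome in the reference sequence used (Release 6), which is the dm6 assembly. Gene models came from Ensembl release 115, which uses the same coordinates. The 3827 IDR peaks were the 3827 regions of highest signal in the pooled list. Replacing the IDR list by as many top regions of the pooled list therefore changes nothing, and that comparison tests nothing. The 24 mitochondrial IDR peaks were set aside for results on location, sequence and genes, a choice made after the list was seen, which left 3803 nuclear peaks.

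Replicates were compared by the share of the top 3827 regions of replicate 1 that overlapped 1 of the top 3827 of replicate 3 by at least 1 bp, against 100 random placements of the replicate 3 regions within their chromosomes. The signal of an IDR peak in a replicate was the highest signal of an overlapping region. Summits were put into classes in the order promoter (within 1000 bp of the TSS of a protein-coding gene), 5′ UTR, 3′ UTR, coding exon, intron and intergenic, and compared with 100 draws of random positions. Motifs were searched on both strands within 50 bp of the summit and in windows of the same width (101 bp) centred 500 bp to each side. Each side was tested with an exact two-sided McNemar test over peaks, and the larger p was kept. Benjamini-Hochberg adjustment covered 15 motifs (AP-1, 5 rearranged controls and 9 others) and, separately, 8192 words of 7 bases. Signals of peaks with and without the AP-1 site were compared by a two-sided permutation test with 100000 resamples. Summit density on X and on the other arms was compared by an exact two-sided binomial test on chromosome length without gaps.

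A total of 25 gene lists were fixed before the data were examined, from textbook knowledge. They cover signalling pathways, stress responses, tissue markers and comparison genes. Some genes stand on several lists, such as kay, puc and msn, so the lists are not independent. Members with a summit within 1000 bp of any TSS were set against all other protein-coding genes on the arms by Fisher's exact test, two-sided. A summit between neighbouring promoters counts for each gene, as for Nmdmc and Rel, which share 1. An alternative drew 10000 random lists matched on gene length (10 bins) and number of TSSs. The symbols d, dys and Dl had no match and were left out, and 4 others were listed under an older symbol (Eip71CD, Eip55E, phl and Jafrac1).

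Genes named in the text follow a rule fixed before the data were examined. They are the protein-coding genes with the TSS nearest to the 20 strongest peaks, applied to nuclear peaks, then Jra and kay, and up to 4 members of each list by signal. For the JNK pathway, JNK and AP-1 target and ecdysone lists any member is named. Intervals on shares are Wilson 95% intervals and cover counting error over peaks or genes, not the spread between animals. With 2 replicates and 1 condition, no test between conditions and no count model could be used, and read depth per library is unknown.

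The word and gene list tests were tested on simulated data. With TGASTCA sites planted in random genomic windows of the size and number used here (3803 windows, 8192 words), the 7-mer test called the AP-1 word when 2% or 4% of windows received it, and not at 0% or 1%. It called 2 other words at 4% and none at 2%. Random windows do not share the promoter setting of the peaks. Words called because base composition differs between summits and flanks were therefore not covered. For lists of 25 genes on a background of 20% among 13945 genes, the gene list test called a list with a true share of 60% in 92% of 200 runs and a list with 40% in 30%. Another list was called in 3.5% to 4.5% of runs.

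Alternatives covered the genome build, a stricter peak set, each replicate alone, promoter and motif windows, flank distance, gene assignment and the matched lists. Peaks in the top regions of both replicates, nuclear regions alone, the JNK list without Jra and egr, and gene bodies against matched lists were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and BLAST 2.17.0.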

Results

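Chromatin bound by Jra was profiled by ChIP-seq in Drosophila melanogaster larvae. Jra is the fly Jun protein, which binds DNA with the Fos protein kay as the AP-1 transcription factor. It acts downstream of the JNK kinase pathway. The animals carried a transgene for Jra with GFP fused to its C terminus, and the precipitation used an antibody against GFP. The material was whole wandering larvae of the third instar, with males and females pooled, so each value is an average over all larval tissues. There was 1 group of 2 biological replicates, labelled 1 and 3. No other condition was part of the design, and control libraries were not analysed here. The comparisons are therefore between the replicates, between peak summits and other sequence, and between groups of genes.

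The authors' list cut by reproducibility between replicates (irreproducible discovery rate, IDR) held 3827 peaks on genome build dm6. These peaks were the regions of highest signal in the pooled list, so a place on it does not mean that each replicate held the peak. Of the 3827 peaks, 3803 lay on the chromosome arms 2L, 2R, 3L, 3R, 4 and X, and 24 lay on the mitochondrial chromosome. Of the 3803, 3765 (99.0%) overlapped a region of both replicate lists, which include background regions. The nuclear peaks were used for every result on location, sequence and genes. Peak signal, the authors' own value for each peak, ranged from 70.6 to 1184 among nuclear peaks. The longer list of replicate 1 held 30000 regions and that of replicate 3 held 29999, background regions included. Read depth is unknown, because the lists hold no read counts.

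The strongest peaks lay at promoters and introns of genes with varied functions. The peak of highest signal (1184) had its summit at 2L 6612709, in an intron of CG11050. Peaks of signal 1056 and 963 followed at the promoters of CG14100 and CG1888. The fourth peak, of signal 929 at 2L 481035, lay in an intron of ush, 1347 bp upstream of the nearest TSS, that of the transcription factor gene cbt. Further peaks among the top 20 lay at the promoters of Ugalt, which encodes a UDP-galactose transporter (signal 924), Lk6, a kinase gene (742), the ESCRT gene CHMP2B (741), the Polycomb group gene ph-p (679) and Sox14, a transcription factor gene of the ecdysone response (673). CG8320 (644), CG8360 (610), CenG1A (604) and Art3 (604) completed the promoter peaks. Intronic summits near the top lay in Zw, the gene for glucose-6-phosphate dehydrogenase (signal 859), osa, a gene of the Brahma chromatin remodelling complex (665), and norpA, which encodes a phospholipase C (601). The peak assigned to CG16753 (728) also lay in an intron, of its neighbour CG32486. CG13323 (778), CG4004 (647) and CG31668 (632) were the nearest genes to intergenic summits. All 20 peaks ranked among the top 3827 regions of each replicate. Of the 20, the Zw peak alone held an exact AP-1 site within 50 bp of its summit.

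The genes for both subunits of AP-1 were themselves among the peaks. At Jra, a peak at 2R 10096990 to 10097310 had its summit 189 bp downstream of the nearest annotated TSS of the gene, with a signal of 461 (rank 48 of 3803). Its signal was 252 in replicate 1 and 210 in replicate 3. Whether reads from the transgene added to this peak is not settled by the lists. At kay, the strongest peak lay 28 bp inside an annotated transcript start (3R 29782637, signal 309, rank 144), with signals of 174 and 135 in replicates 1 and 3. There were 3 weaker peaks at kay, of signal 103, 83.6 and 77.5. The peak of signal 103, in an intron, held an AP-1 site within 50 bp. No AP-1 site lay within 50 bp of the promoter summits of Jra and kay.

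The 2 replicates shared most of their strongest regions. Of the 3827 regions of highest signal in replicate 1, 2653 overlapped 1 of the 3827 highest in replicate 3 by at least 1 bp (69.3%, Wilson 95% interval 67.8 to 70.8). Random placement of the replicate 3 regions on their chromosomes gave a mean overlap of 2.35% and at most 3.27% in 100 draws. Among nuclear IDR peaks, 2628 (69.1%) overlapped the top 3827 regions of both replicates. A further 645 did so in replicate 1 alone, 455 in replicate 3 alone and 75 in neither. Signals in the 2 replicates had a Spearman rho of 0.59 and a Pearson r of 0.68 on log2 values across 3765 peaks, which are not independent replicates. The peaks were chosen by the pooled signal of the same 2 libraries. These coefficients therefore describe the chosen peaks and do not measure agreement over all regions. The JNK pathway genes Jra, Mkk4, kay, POSH, aop and puc stood among the stronger peaks in both libraries. The peak at egr, which encodes the TNF ligand of the pathway, had no overlapping region in the replicate 1 list. Its signal was 39.1 in replicate 3.

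**Figure D1:**
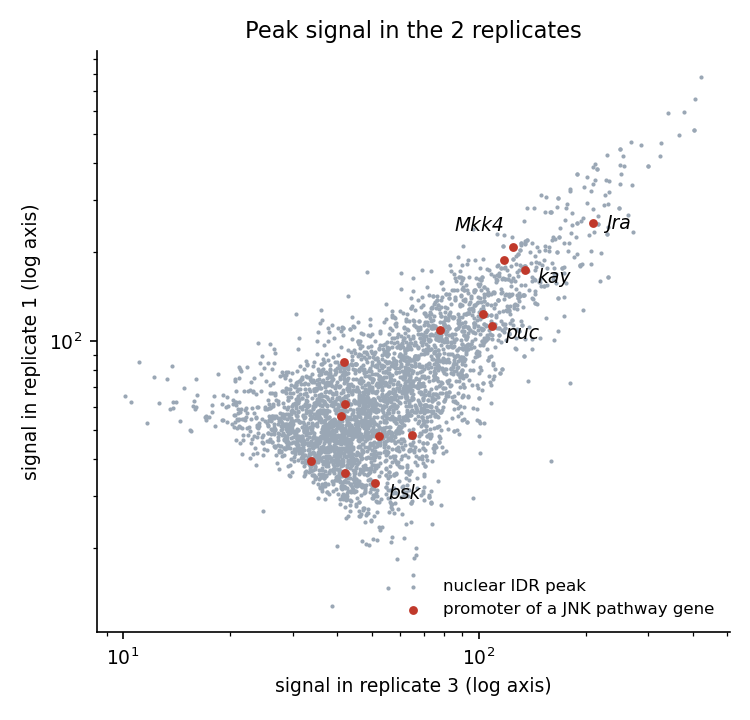
Signal of nuclear IDR peaks in replicate 3 (x axis) and replicate 1 (y axis), both on log axes in the authors' signal units, for peaks with a region in both lists. Each grey point is a peak and red points are promoter peaks of JNK pathway genes, with 5 of them named. Jra, with signals of 252 and 210, lies toward the upper end.

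Peaks were concentrated at promoters. Of 3803 nuclear summits, 2437 lay within 1000 bp of the TSS of a protein-coding gene (64.1%, Wilson 95% interval 62.5 to 65.6). Random positions drawn in the same number per chromosome did so in 20.4% on average and in at most 22.1% of 100 draws. The share at peaks was 3.15-fold that of random positions and above all 100 draws. Introns held 915 summits (24.1%, against 36.4% of random positions) and intergenic sequence 410 (10.8%, against 28.3%). Coding exons away from promoters held 5 summits (0.131%, against 10.1% of random positions, and 7 and 2 in the top regions of replicates 1 and 3 alone), and 3′ UTRs held 27 (0.710%, against 4.38%). The 9 summits in 5′ UTRs outside promoters (0.237%) were at the lowest share that the random draws gave.

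**Figure D2:**
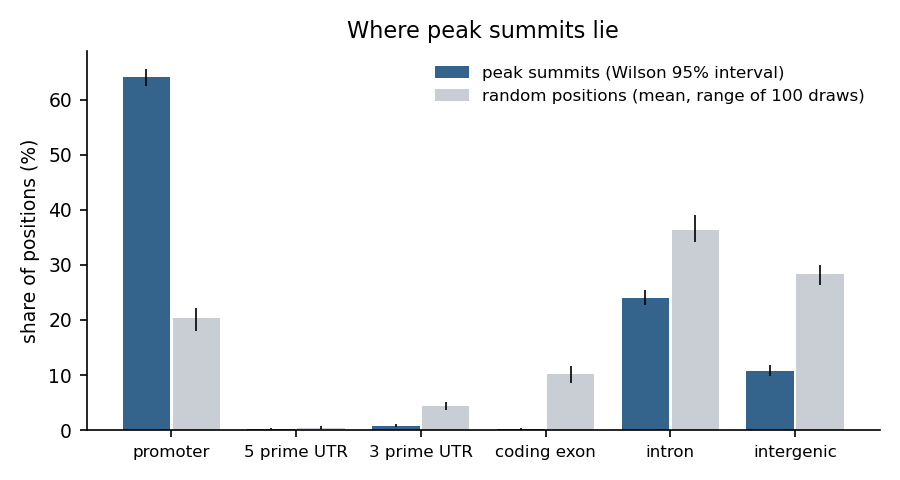
Share of positions (%) in each class of gene feature, for 3803 nuclear peak summits (blue, with Wilson 95% intervals) and for random positions (grey, mean and range of 100 draws). Promoters are positions within 1000 bp of a protein-coding TSS, and hold 64.1% of summits.

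The AP-1 site was enriched at the summits but present at a small share of them. The sequence TGASTCA (S is C or G), the textbook AP-1 site, lay within 50 bp of 155 summits (4.08%, Wilson 95% interval 3.49 to 4.75). In windows of the same width centred 500 bp to the left and right of the same summits, it lay in 0.868% and 0.736%. The share at summits was 5.08-fold that of the flanks (exact McNemar tests, two-sided, p = 4.2e-20 and 1.6e-22). The share was 3.68% in the top regions of replicate 1 and 3.52% in those of replicate 3. It was 2.34% within 25 bp of the summit. Among the 155 peaks with a site, the median distance from summit to site was 20 bp, and 44 peaks held it within 10 bp. The search within 50 bp bounds this distance, so it does not by itself measure centring. With 1 mismatch allowed outside the central base, 19.5% of summits and 13.1% of flanks held the site. Of 5 rearrangements of the AP-1 sequence used as controls, AGTSACT was also higher at summits (1.66% against 0.684%, exact adjusted p = 0.0025) and GATSATC was lower (0.447% against 0.999%, adjusted p = 0.033). Neither passed in the top regions of replicate 1 alone (exact adjusted p = 0.21 and 0.35), and GATSATC did not pass in the 1901 peaks of higher signal (exact adjusted p = 0.68). GTASTAC was higher in the top regions of replicate 3 alone (exact adjusted p = 0.049).

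**Figure D3:**
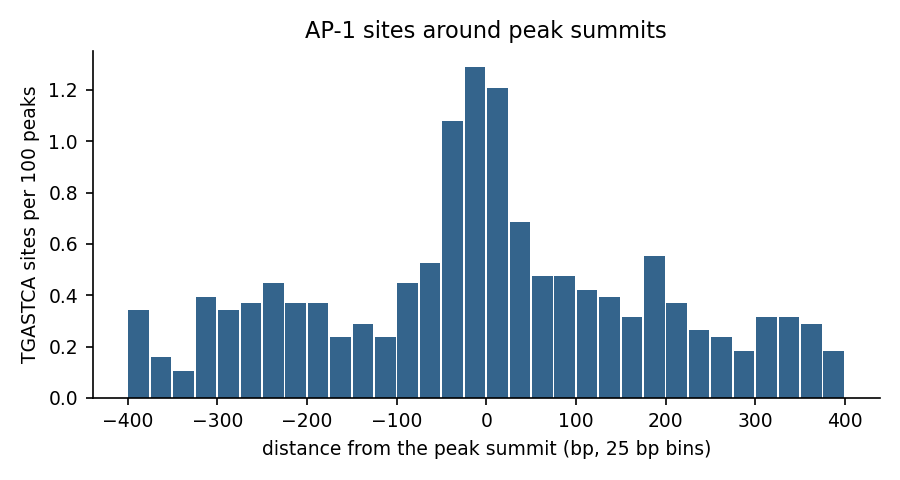
AP-1 sites (TGASTCA) per 100 nuclear peaks (y axis) in bins of 25 bp by distance from the peak summit in bp (x axis). Sites are most frequent in the bins next to the summit, and 44 of the 155 peaks with a site within 50 bp hold it within 10 bp.

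Peaks with and without the AP-1 site had about the same signal. The median signal was 108 for 155 peaks with it and 104 for 3648 without it, a difference of 0.05 on the log2 scale (two-sided permutation test, p = 0.38). In 5 groups of peaks of nearly equal size, ordered from the strongest signal to the weakest, 5.12%, 4.07%, 3.15%, 4.21% and 3.82% of peaks held the site. Of the 100 strongest peaks, 3 did (Wilson 95% interval 1.03% to 8.45%). Peaks away from promoters held it more often, at 72 of 1366 (5.27%), than promoter peaks, at 83 of 2437 (3.41%, Fisher's exact test, p = 0.0062). Most AP-1 sites of the genome lay away from peaks. Of 11142 on the chromosome arms, 163 (1.46%) were within 50 bp of a summit, with 3.61% of those at promoters, 1.21% of those in introns and none of 703 in coding exons (Wilson upper bound 0.543%).

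The DNA replication-related element (DRE), TATCGATA, had a higher fold over its flanks than the AP-1 site, but lay at fewer summits. This sequence is found at promoters of broadly expressed fly genes. It lay within 50 bp of 123 summits (3.23%) and in 0.289% of flanks, an 11.2-fold difference (exact McNemar tests adjusted over 15 motifs by Benjamini-Hochberg, p = 3.5e-23). The fold was 8.52 in the top regions of replicate 1 alone and 8.48 in those of replicate 3 alone. Of the 123 peaks with it, 121 were at promoters. Away from promoters, 0.146% of peaks held the DRE and 5.27% the AP-1 site. The E box CACGTG was lower at summits than in flanks (0.841% against 1.50%, exact adjusted p = 0.033), but not in the top regions of either replicate alone (adjusted p = 0.40 in replicate 1 and 0.20 in replicate 3). Sites for GAGA factor, GATA factors, Grh, Zelda, TEAD factors and CREB, and the E box CAGCTG, passed no test. The GAGA sequence GAGAGAG lay at 3.34% of summits and 2.55% of flanks (exact adjusted p = 0.23). In the top regions of replicate 3 alone it passed, at 4.05% against 2.56% (exact adjusted p = 0.010).

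All 8192 words of 7 bases, each merged with its reverse complement, were then compared in the same way. At an adjusted p below 0.05, 219 words were more frequent at summits and 223 less frequent. In the 1901 peaks of higher signal these counts were 113 and 53. The words ATCGATA (6.60% of summits, 1.22% of flanks), CTATCGA and ACTATCG, which overlap the DRE or share its core, came first. The AP-1 word TGACTCA was the fourth. Its rank was 5 in the top regions of replicate 1 alone and 11 in those of replicate 3 alone, where TTTAAAA came first. A/T-rich words such as TTTAAAA (10.5% against 5.11%) came next, with AACACTG (3.52% against 0.973%). The word most reduced at summits by its p was CTCCTCC (0.526% against 2.96%). Flank windows were not matched to summits on gene feature class. Words that differ for base composition of these classes therefore cannot be told apart from words linked to binding.

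Genes of the JNK pathway held promoter peaks more often than other genes. Among 13945 protein-coding genes, 2839 (20.4%) had a summit within 1000 bp of a TSS. In the JNK pathway list, 16 of 25 genes did (64.0%, odds ratio 6.99, exact adjusted p = 2.1e-05, from Fisher's test with Benjamini-Hochberg adjustment over 25 lists). In the 1901 peaks of higher signal, 9 of 25 did (36.0%, odds ratio 4.11, exact adjusted p = 0.0074). After Jra, these were Mkk4, a kinase that activates JNK (signal 329), kay (309), the scaffold gene POSH (294), aop, which encodes an ETS repressor (232, with an AP-1 site within 50 bp), the JNK phosphatase gene puc (213) and raw (188). Weaker peaks lay at Traf6 (125), CYLD (110), egr (96.4), Cdc42 (94.9), Traf4 (94.7), the JNK gene bsk (87.6), msn (83.9), Tak1 (81.5) and Src64B (81.2). No promoter summit was listed at hep, slpr, Ask1, wgn, grnd, Rac1 or Src42A, and wnd and Tab2 had summits elsewhere in the gene or upstream. Without Jra, the tagged gene, and egr, which lies near it, 14 of 23 genes had a promoter peak (odds ratio 6.11, Fisher's exact test, p = 2.6e-05). Against 10000 random lists matched on gene length and number of TSSs, which held 27.9% on average, the JNK list was again higher (permutation test, adjusted p = 0.0033). The random lists were not matched on expression. Binding directed at this pathway therefore cannot be told apart from peaks shared by active promoters.

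Of 24 genes reported as targets of JNK or AP-1, 12 had a promoter peak (odds ratio 3.92, exact adjusted p = 0.0048). The highest signals were at Mmp1, which encodes a matrix metalloproteinase (309), kay (309), the ETS factor gene Ets21C (237), Atf3 (230) and puc (213). The pro-apoptotic gene hid (160), scaf (99.4), chinmo (96.3), msn (83.9), Thor (75.7), rpr (74.1) and ftz-f1 (72.0) also held promoter peaks. Socs36E and the cytokine gene upd3 had none at their promoters, but had summits in the gene or within 2000 bp upstream with signals up to 284 and 259. The same held for zip and mol, with signals up to 117 and 90.8. No summit lay in the gene or within 2000 bp upstream at Ilp8, Mmp2, wg, Wnt6, upd1, upd2, cher or Gadd45. By the gene with the nearest TSS to each summit, 20 of the 24 targets had a peak (odds ratio 22.2, exact adjusted p = 8.5e-11), so some of these 8 genes have peaks farther away. This assignment was not tested against matched lists. Some other lists rose by it too, such as imaginal disc patterning (18 of 23, odds ratio 16.0). Of 16 genes for bZIP transcription factors, the class to which Jra belongs, 9 had a promoter peak (odds ratio 5.04, exact adjusted p = 0.0060). After Jra and kay the strongest were Irbp18 (246) and Atf3 (230). In the permutation test against matched random lists, neither the target list nor the bZIP list passed (adjusted p = 0.14 for each). With summits in the gene body or up to 2000 bp upstream counted, the target list passed against matched lists (16 of 24 against 39.7%, permutation test, adjusted p = 0.032). The target list did not pass in the 1901 peaks of higher signal (exact adjusted p = 0.19), nor the bZIP list with a window of 250 bp (exact adjusted p = 0.073).

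Genes of Hippo signalling, a pathway of growth control, held promoter peaks in 10 of 16 (odds ratio 6.54, exact adjusted p = 0.0018), with 9 of 16 in the top regions of replicate 1 alone (odds ratio 4.75) and 12 of 16 in those of replicate 3 alone (odds ratio 11.7). The 10 genes included the apoptosis inhibitor gene Diap1 (229), the kinase gene hpo (191), ds (177) and ex (153). The list passed the permutation test against matched random lists (adjusted p = 0.022), but not Fisher's exact test with promoter windows of 250 bp (adjusted p = 0.073) or 500 bp (adjusted p = 0.052). Genes of actin, adhesion and matrix held 14 of 28 (odds ratio 3.93, exact adjusted p = 0.0022). Among them were the profilin gene chic (484), the myosin light chain gene sqh (380, with an AP-1 site), Arp3 (198) and the vinculin gene Vinc (193). EGFR signalling and heat shock genes each held 8 of 17 (odds ratio 3.48, exact adjusted p = 0.034). The highest signals were at aop (232), Ras85D (132) and spi (129) for EGFR signalling, and at Hsp27 (383), Hsp26 (203) and Hsp83 (131) for heat shock. The EGFR list did not pass in the top regions of replicate 3 alone (exact adjusted p = 0.11), nor the heat shock list in those of replicate 1 alone (adjusted p = 0.16). Neither passed in the 1901 peaks of higher signal (exact adjusted p = 0.66 and 0.35), among peaks in the top regions of both replicates (0.077 for each) or with a window of 500 bp (0.059 for each). The heat shock list also did not pass with a window of 250 bp (exact adjusted p = 0.33). In the permutation test against matched random lists, the actin, EGFR and heat shock lists did not pass (adjusted p = 0.24, 0.24 and 0.14). When summits in the gene body or up to 2000 bp upstream were counted, the EGFR list passed against matched lists (12 of 17 against 39.1%, permutation test, adjusted p = 0.041).

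The 2 comparison lists with the clearest outcome lay at opposite ends. Genes of cytoplasmic ribosomal proteins, which nearly all growing cells use, held promoter peaks in 55 of 85 (64.7%, odds ratio 7.29, exact adjusted p = 1.8e-17, and 29 of 85 in the 1901 peaks of higher signal, odds ratio 3.82), with signals of 303 at RpL34b, 247 at RpL32 and 227 at RpS20. Chemoreceptor genes held them in 2 of 179 (1.12%, odds ratio 0.044, exact adjusted p = 3.3e-14), at Ir60e (185) and Gr32a (101). The shares of the JNK and ribosomal protein lists differed by -0.71 percentage points (95% interval -22.1 to 20.7, Fisher's exact test, p = 1). No gene list was compared with genes of like expression. A higher share in any list, the JNK, target, bZIP and Hippo lists included, may thus follow promoter activity in general.

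Ecdysone response genes, active at the end of larval life, held promoter peaks in 10 of 25 (odds ratio 2.61, exact adjusted p = 0.052), which did not pass. The count was 12 in the top regions of replicate 3 alone, which passed (exact adjusted p = 0.0066), and 8 in those of replicate 1 alone, which did not (adjusted p = 0.32). The list also passed with a promoter window of 2000 bp (13 of 25, exact adjusted p = 0.010), but not with windows of 250 or 500 bp (6 of 25 each, 0.40 and 0.54). It did not pass in the 1901 peaks of higher signal (5 of 25, exact adjusted p = 0.45) or among peaks in the top regions of both replicates (7 of 25, 0.18). The signals were 192 at Eip75B, 169 at Eip74EF, 152 at usp and 128 at EcR, the last 2 encoding the ecdysone receptor. They were 107 at Eip63E, 104 at crol, 103 at Kr-h1, 93.0 at br, 73.0 at Hr39 and 72.0 at ftz-f1. With summits in the gene body or up to 2000 bp upstream counted, the list passed (odds ratio 5.43, adjusted p = 1.2e-04), but not in the permutation test against random lists matched on length and number of TSSs (16 of 25, adjusted p = 0.14). Eip78C, Hr4 and ImpL2 had such summits, with signals up to 373, 256 and 259. Oxidative stress genes held promoter peaks in 8 of 19 (exact adjusted p = 0.081), among them Sesn (333), Nmdmc (235), Keap1 (187) and Sod2 (130). This list passed in the 1901 peaks of higher signal (7 of 19, exact adjusted p = 0.018), among peaks in the top regions of both replicates (7 of 19, 0.049) and with a window of 2000 bp (10 of 19, 0.026). It passed in the top regions of neither replicate alone (exact adjusted p = 0.28 in replicate 1 and 0.082 in replicate 3).

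Marker genes of single larval tissues did not pass by promoter peaks of the IDR list, but the fat body, larval cuticle and neuron lists passed under some alternatives. Promoter peaks were found at 4 of 15 fat body genes (Lpin, signal 293), 3 of 16 salivary gland genes (fkh, 577), 3 of 19 muscle genes (Zasp52, 118), 2 of 17 neuron genes (elav, 189) and 4 of 11 glia genes (moody, 217). They were found at 1 of 16 haemocyte genes (ush, 159), 1 of 18 midgut digestion genes (nub, 108), 0 of 11 tracheal genes and 0 of 20 larval cuticle genes (exact adjusted p = 0.052). A count of 0 of 20 allowed a share of up to 16.1% (Wilson upper bound). The cuticle list passed as lower in the top regions of replicate 1 alone (exact adjusted p = 0.035), of replicate 3 alone (0.049) and with a window of 2000 bp (0.016), but not against matched lists (0.23). The fat body count was 7 of 15 in the top regions of replicate 3 alone, which passed as higher (exact adjusted p = 0.049), and 4 of 15 in those of replicate 1 alone. Immune response genes held promoter peaks in 6 of 26 (imd, 367), wound response genes in 6 of 18, JAK-STAT genes in 4 of 13 and imaginal disc patterning genes in 8 of 23 (dac, 148). The JAK-STAT count was 5 in the top regions of replicate 1 alone and 2 in those of replicate 3 alone. Chorion and vitelline genes, which are active in the adult ovary, held them in 0 of 16 (exact adjusted p = 0.11), and passed as lower with a window of 2000 bp (0.034). With summits in the gene body or up to 2000 bp upstream counted, the JAK-STAT and imaginal disc lists passed as higher (Fisher's exact test, adjusted p = 0.041 and 6.1e-06). Against matched lists by this measure, the JAK-STAT list did not pass (7 of 13 against 36.1%, permutation test, adjusted p = 0.36).

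**Figure D4:**
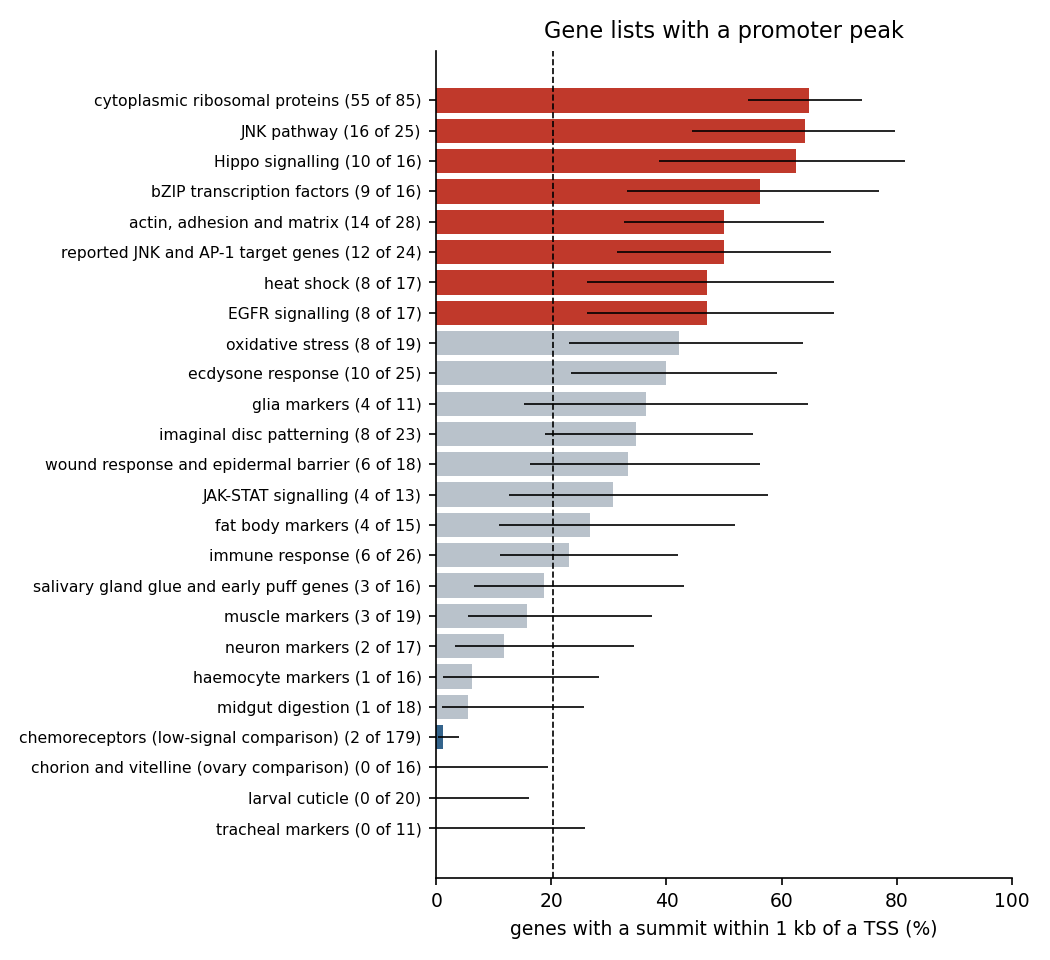
Share of genes (%) with a nuclear peak summit within 1 kb of a TSS for 25 gene lists, with Wilson 95% intervals. Red bars are higher and the blue bar is lower than other genes at an adjusted p below 0.05, grey bars passed no test, and the dashed line marks the 20.4% of all protein-coding genes. Ribosomal protein genes (55 of 85) and JNK pathway genes (16 of 25) have the highest shares.

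Peak density was similar on the large chromosome arms. There were 29.9 nuclear summits per Mb on 2L, 29.1 on 2R, 28.5 on 3L, 28.3 on 3R and 27.4 on X. Chromosome 4, of 1.33 Mb, held 16 summits. The density on X was 0.957 times that on the other arms (95% interval 0.878 to 1.04, exact binomial test, p = 0.32). In the top regions of replicate 3 alone the ratio was 0.848 (exact p = 2.1e-04), and in those of replicate 1 alone 0.978 (p = 0.63). Among peaks in the top regions of both replicates, a set chosen after seeing the data, it was 0.848 (exact p = 0.0021).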

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

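The tests in this part and their limits were chosen after the mitochondrial peaks had been seen. The IDR list held 24 mitochondrial peaks, a signal outside the chromosome arms on which the results above rest, and the strongest of them had the highest signal of the whole list (3292). The list of replicate 3 held 28 mitochondrial regions and that of replicate 1 held 0. On build dm3, the IDR list held 3 mitochondrial peaks and replicate 3 held 11 regions, with signals of at most 93.7 and 157.

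The regions of replicate 3 on dm6 covered 84.4% of the mitochondrial chromosome, as an excess of mitochondrial DNA over the control in that replicate may give without local binding. The same replicate held 28 mitochondrial regions on dm6 but 11 on dm3. Such an excess alone does not account for this difference between builds, and its cause was not tested. Reads from copies of mitochondrial DNA on the chromosome arms are argued against for 22 of the 24 peaks, whose sequences had no match there of 100 bp or more at 95% identity. For the other 2 peaks, which matched 1 nuclear location, this source cannot be told apart from mitochondrial reads, because the lists hold no reads. No IDR peak lay at that location. Copies on nuclear sequence outside the arms are not covered. The design has 1 group, so no biological explanation was tested.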

How the results depend on the processing

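Most results kept their direction and their side of the threshold. Of the alternative values for the main results, 56 did so or stayed within 1.5 times, 3 passed a threshold that the main value did not, and 5 counts moved by more. No value that passed its test in either version changed direction. Values that passed in neither did in places, as the log2 difference in signal with the AP-1 site, 0.05, which was -0.01 with a motif window of 100 bp. The share of replicate 1 top regions found in replicate 3 ranged from 57.6% (summits within 100 bp) to 69.7% (top 5000 regions), and the promoter share from 46.5% (window of 250 bp) to 74.2% (2000 bp). The AP-1 share exceeded its flanks in each alternative, from 2.34% within 25 bp of the summit to 5.89% within 100 bp, and 19.5% with 1 mismatch. No difference in signal with the AP-1 site passed its test under any alternative run (permutation p from 0.073 to 0.87). The signal correlation was 0.56 to 0.59.

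The X to autosome ratio of density, 0.957, passed its exact test under 3 alternatives. These were the peaks of higher signal, 0.879, peaks in the top regions of both replicates, 0.848, and replicate 3 alone, 0.848. With replicate 1 alone it was 0.978 and did not pass. The number of gene lists with more promoter peaks, 8, fell to 5 with windows of 250 bp, to 5 with windows of 500 bp and to 3 against lists matched on length and number of TSSs. It rose to 10 with windows of 2000 bp, to 11 with gene bodies and to 12 by nearest TSS. With each replicate alone it was 7 and 9. Words of 7 bases higher at summits numbered 113 in the 1901 peaks of higher signal, a set with fewer peaks, against 219, and lower words 53 against 223. With each replicate alone, other motifs called higher numbered from 1 to 2, and the AP-1 word ranked 5 and 11 against 4. The cause of these changes was not tested. For single lists, motifs and peak ranks, 638 alternative values stayed, 20 passed a threshold that the main value did not, 21 no longer passed and 51 ranks moved out of the top 3827 regions of a replicate.

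The pooled list gave the IDR peaks again, so that alternative tests nothing, though its values are among those counted as unchanged. The dm3 alternatives for promoter share, AP-1 share, motif and signal, chromosome density and gene lists were not run, since a dm3 genome and annotation were not used here. Read depth is unknown, so its effect on weaker peaks cannot be given. No paired analysis was possible because there is 1 group.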

Other observations

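Of the tests below, those of a summit off the site for most peaks and of sites with 1 mismatch were chosen, with their limits, after the values they rest on had been seen. Those of gene bodies against matched lists, flanking bases, other elements and replicate ratios were also chosen after the data had been seen. Imaginal disc patterning genes held peaks more often than matched lists when summits away from promoters were counted too. With summits in the gene body or up to 2000 bp upstream counted, 17 of 23 had a peak (73.9%), against 42.5% in lists matched on length and number of TSSs (permutation test, adjusted p = 0.025). Neuron genes were lower by the same measure, at 3 of 17 against 48.5% (permutation test, adjusted p = 0.041), but not against all other genes (24.7%, Fisher's exact test, adjusted p = 0.85) or by promoter peaks against matched lists (adjusted p = 0.15). Annotated transposable elements held 3 of 3803 summits (0.079%), against 5.88% of random positions. Random positions covered all sequence outside gaps, with no filter for repeats, so this low share cannot be read as a lack of binding. Within 500 bp of ncRNA genes lay 9.18% of summits, against 5.54% and at most 6.65% in 100 draws. For tRNA, snRNA and snoRNA genes the shares were 2.19, 3.88 and 2.26 times the random mean (15, 4 and 11 summits) and no higher than the highest draw.

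The AP-1 sites near summits differed from other AP-1 sites in flanking bases, both next to the site and farther out. Read so that the central base is C, 36.8% of the 163 sites within 50 bp of a summit had A before TGACTCA and 30.1% had G, against 26.0% and 20.4% of 10277 sites more than 1000 bp from any summit (Fisher's exact test, adjusted p = 0.043 for each). T stood there in 14.7% against 26.7% (exact adjusted p = 0.014). A was rarer just after the site (19.6% against 29.6%, exact adjusted p = 0.043). T was rarer 7 bases before the central base (22.7% against 32.4%) and G more frequent 6 bases after it (31.3% against 22.1%, exact adjusted p = 0.046 for each). The site sets were not matched on gene feature class: promoters held 87 of the 163 sites near summits and 2407 of all 11142. A binding preference therefore cannot be told apart from local base composition. Ribosomal protein promoters had a higher ratio of replicate 1 to replicate 3 signal than other promoters, with medians of 0.55 and 0.31 on the log2 scale (59 and 2341 peaks, permutation test across peaks, p = 0.0065). Peaks on X had a median of 0.39 and those on the autosomes 0.28 (permutation test across peaks, p = 1.6e-04). These tests compare 2 libraries.

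A total of 3648 nuclear peaks held no exact AP-1 site within 50 bp of the summit. That weak or irreproducible calls set these peaks apart from those with the site is argued against. Peaks with and without the site were in the top regions of both replicates at 70.3% and 69.1%, a difference of 1.27 percentage points (95% interval -6.08 to 8.62). Both groups were cut at the same pooled signal, which limits how far they can differ. Weak calls at like rates in both groups stay possible. A summit placed off the site is argued against for most of the 3648 peaks, since 5.15% held a site 51 to 220 bp away. It stays open for a few, since that share was 1.41 times the share 1000 bp away (95% interval 1.17 to 1.70). Sites with 1 mismatch exceeded the flanks by 2.88 percentage points, too few for most of these peaks. A candidate explanation that stays open is open promoters shared by many factors and by background of the precipitation. Peaks without the site lay at promoters in 64.5% and peaks with it in 53.5%, a difference of 10.98 percentage points (95% interval 2.98 to 18.98). Most peaks of either group were thus at promoters. These counts are those compared above for promoter and other peaks, so they add no separate evidence. No biological explanation was tested.

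The peak at Jra might reflect extra copies of the transgene as well as binding. Within 20 kb of the Jra TSS, the pooled list held 17 regions, against a median of 10 around other protein-coding TSSs, which put it at the 76.8 percentile. Extra copies were predicted to place it above the 95th percentile and their absence below the median, so they cannot be told apart from binding here. The reach of the transgene is not given in the sources used here, and reads of an untagged strain were not analysed here.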
